A study of Mus musculus with 32 samples.

How the data were processed

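Liver RNA of 32 female ApoE3Leiden mice was measured on Illumina mouse bead arrays, 1 liver per array and 8 livers in each of 4 groups, as the labels assign them. The labels speak of further samples, which are not analysed here. The livers came from separate animals, 1 per array, so p-values refer to the spread between animals together with that between arrays and, unless chip was a block, between chips.

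The authors deposited a table of probe intensity per array, not normalized between arrays, from which a background level had been subtracted, since some values lie below 0; how this was done is not given in the sources used here. The authors deposited beside each intensity a detection value as a fraction from 0 to 1, of which 1 minus the value served as the detection p. The authors deposited log2 values of 15505 of the 25697 probes in a second table, which were quantile normalized to judge from their distributions and made with limma per the submitters' processing notes; the filter behind this selection is not given in the sources used here.

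The intensities were background corrected with limma's normal-exponential model using the detection p and an offset of 16, quantile normalized and put on the log2 scale (R 4.3.3, limma 3.58.1). Probes with a detection p under 0.05 on at least 8 of the 32 arrays were kept, 12844 in number. Of these 12026 had 1 gene name, 0 had several and 818 were not named. Gene symbols came from the platform's annotation, updated through the Entrez ID for 14548 of 14557 named probes, through an accession for 7 and taken as they stood for 2. For the 2283 genes with more than 1 kept probe the probe with the highest mean was used, which left 8853 genes. Some genes of the rule below are not reported here. The highest correlation between 2 arrays was 0.989, and no 2 arrays held identical values.

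A linear model of the 4 groups was fitted to all 32 arrays with limma's lmFit and eBayes, so that all comparisons shared 1 estimate of the spread (28 residual degrees of freedom; median residual SD 0.316). There were 6 pairwise comparisons and the interaction of the 2 drugs, each adjusted by Benjamini-Hochberg over the genes with a threshold of 0.05. For 29 gene lists with 485 genes, 387 of them measured, limma's camera was run with its preset correlation of 0.01 and again with an estimated correlation, and members were also adjusted over the list alone. With the estimated correlation 0 of the 10 list calls held. The mean intensity per array was 189.3 ± 45.7 (SD, n = 32).

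The groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, in each comparison with HC, a set of sterol, bile acid and acute phase genes (Sqle, Insig1, Srebf2, Srebf1, Cyp7a1, Abcg5, Abca1 and Saa1 as far as measured). In every comparison it named the 5 genes with the largest and the 5 with the smallest log2 difference among those past the threshold, and up to 4 members of a described list past the threshold. List members named that did not pass over all genes were chosen as examples after their values were seen, as were the genes given from the fit with chip as a block.

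The alternatives were no background correction, scaling to equal medians, cyclic loess, the authors' normalized values, no filter or a stricter one (detection p under 0.01 on 16 arrays), every kept probe, chip as a fixed or random block, array position as a covariate, the replicate number as a block, array weights, a variance trend with robust estimation, only the groups compared, and leaving out each array in turn. Leaving out the 4 arrays with the lowest mean correlation, doing so with chip as a block, and chip as a block with array weights were chosen after seeing the data, as were 2 comparisons averaged over the other drug.

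The procedure was tested on simulated data of the size of HC+RSV against HC, with 200 of 8853 genes changed. It recovered 36.5% of genes changed by 0.5 on the log2 scale, 92.8% of those changed by 1 and 99.5% of those changed by 2, with 4.7% false calls. A list shifted by 0.3 was called in 8 of 20 runs. The simulated noise was drawn independently for each gene and array, without chip effects or arrays that stand apart. These rates may therefore not carry over to the real arrays.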

Results

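Gene expression was measured in the livers of female ApoE3Leiden mice, a transgenic strain that carries a variant of human apolipoprotein E and develops raised plasma cholesterol when fed cholesterol. All mice received a high-cholesterol diet (HC). They received it alone, with rosuvastatin (HC+RSV), with ezetimibe (HC+EZE) or with both drugs (HC+RSV+EZE). Rosuvastatin is a statin, a drug that lowers cholesterol synthesis, and ezetimibe blocks uptake of cholesterol from the intestine. Each group held 8 livers, each on its own Illumina bead array, 32 arrays in all. The mean intensity per array ranged from 126.1 to 279.9 before normalization and 10724 to 13444 probes per array were detected. The mean number of detected probes was 11928 ± 699 (SD, n = 8) in HC, 11701 ± 824 in HC+RSV, 11478 ± 457 in HC+EZE and 11417 ± 485 in HC+RSV+EZE. After a filter on dim probes 8853 named genes were tested. Values below are log2 intensities, differences carry the standard error of the fit, and adjusted p-values are limma's after Benjamini-Hochberg adjustment. The number of arrays limits the precision: the median standard error of a difference between groups was 0.16.

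The arrays lay on 6 chips, each of which held arrays of all 4 groups. The first principal component took up 29.7% of the variance between arrays and chip membership accounted for 67% of the second. Array position on the chip ran with the groups: arrays without ezetimibe sat at positions A to C and arrays with ezetimibe at positions F to H. Within these, HC lay at A and B, HC+RSV at B and C, HC+EZE at F and G and HC+RSV+EZE at G and H. Position therefore ran in part with rosuvastatin too, so comparisons for either drug are mixed with it. The 4 arrays with the lowest mean correlation with the other arrays were HC replicates 1 and 8 (0.937 and 0.949), HC+RSV replicate 3 (0.926) and HC+EZE replicate 1 (0.951). None of these 4 was an HC+RSV+EZE array. In these 4 arrays the median difference from the other arrays was -1.04 for genes of oxidative phosphorylation, 0.52 for genes of bile acid synthesis and transport and -0.39 for macrophage markers.

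**Figure D1:**
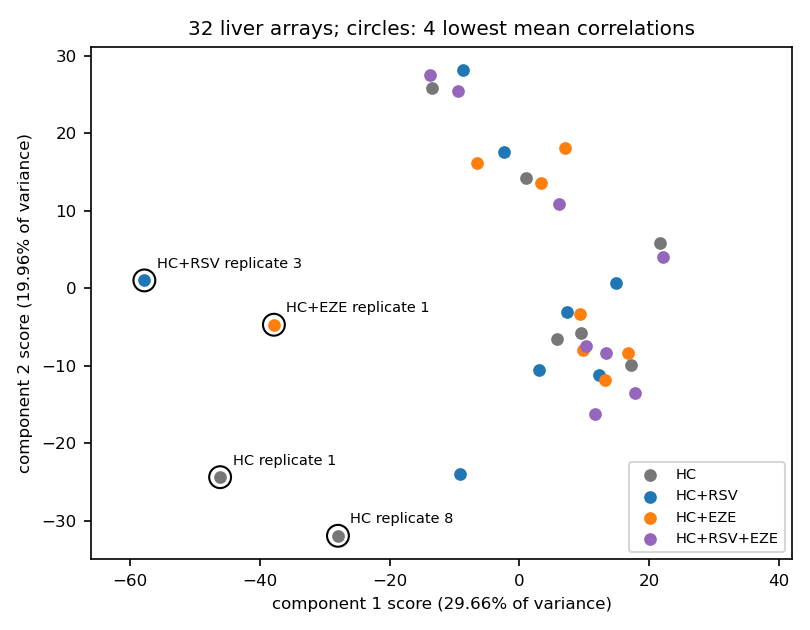
Scores of the 32 liver arrays on the first (x axis, 29.7% of the variance) and second (y axis) principal component of the log2 intensities, coloured by group, with the 4 arrays of lowest mean correlation circled. HC replicates 1 and 8, HC+RSV replicate 3 and HC+EZE replicate 1 have first component scores of -46.1, -28.0, -57.8 and -37.8 and lie apart from the other 28 arrays.

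The comparison of HC+RSV with HC asked what the statin alone did to liver expression. The markers of macrophages, the resident and recruited phagocytes of the liver, were lower as a group: all 13 measured members had negative differences, with a mean of -0.32 (camera, adjusted p = 0.00083). With an estimated correlation between genes this shift had an adjusted p = 0.852. Vsig4, a complement receptor of Kupffer cells, differed by -0.49 ± 0.20, Adgre1, a surface marker of macrophages, by -0.49 ± 0.25 and Clec4f, a Kupffer cell lectin, by -0.28 ± 0.19. None of the 13 passed the test singly, over all genes or adjusted over the list alone. The list was lower on 5 of the 6 chips, and camera's adjusted p was 0.00636 with chip as a block. HC holds 2 and HC+RSV 1 of the 4 arrays that stood apart. Without all 4 the macrophage list had an adjusted p of 0.0501, and oxidative phosphorylation genes, at a mean of 0.08 with all arrays (adjusted p = 0.306), were lower as a group (0.000831). With an estimated correlation and all arrays no list passed in this comparison (camera, smallest adjusted p = 0.852).

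Genes of cholesterol synthesis had a mean difference of 0.20 in HC+RSV, with 13 of 15 members above 0, and did not pass (camera, adjusted p = 0.114). The direction of this list turned without the 4 arrays that stood apart (adjusted p = 0.829), where Sqle differed by 0.32 and Lss by 0.082. With all arrays Sqle, which encodes squalene epoxidase of that pathway, differed by 0.67 ± 0.50 (8 livers per group) and did not pass. Its other kept probe differed by 0.76 ± 0.49. With chip as a block Sqle differed by 0.57 ± 0.28 (limma, adjusted p = 0.997), and it was higher on 6 of 6 chips, by 0.165 to 1.003. Lss, lanosterol synthase, differed by 0.37 ± 0.30 and Cyp51, lanosterol demethylase, by 0.40 ± 0.34 with all arrays. Srebf2, the transcription factor that drives this pathway, differed by 0.17 ± 0.16, and Insig1, a sterol-regulated retention factor of SREBP processing, by 0.22 ± 0.34. Srebf1, the regulator of fatty acid synthesis, differed by 0.38 ± 0.27. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.49 ± 0.27. The sterol exporters Abcg5 and Abca1 differed by -0.10 ± 0.19 and -0.13 ± 0.12, and Saa1, an acute phase gene, by -0.01 ± 0.42. Saa1 was near background, detected on 2 of 8 HC, 4 of 8 HC+RSV, 1 of 8 HC+EZE and 5 of 8 HC+RSV+EZE arrays. The direction of Saa1 turned with the authors' values (0.11), with chip as a block (0.17) and with array weights (0.004), that of Abcg5 without the 4 arrays (0.055) or HC replicate 8 (0.009), and that of Insig1 with array weights (-0.001).

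No gene passed the threshold between HC+RSV and HC: limma called 0 of 8853 genes, 235 (2.65%) had an unadjusted p under 0.05, and with chip as a block the count was 0 again, with 384 at an unadjusted p under 0.05. Adjusted over the list alone, 0 members of any of the 29 lists passed. With chip as a block 3 lists passed camera's test, macrophage markers among them, against 1 without the block and 0 with an estimated correlation. Without HC replicate 7 the macrophage list no longer passed (adjusted p = 0.167), nor did it without HC+RSV replicate 3.

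The comparison of HC+EZE with HC asked what ezetimibe alone did. In all, 3 genes rose and 1 fell. Usp2, a clock-controlled deubiquitinase, rose by 2.04 ± 0.38 (4.11-fold, limma, adjusted p = 0.0163), and Ciart, a repressor within the clock, rose by 1.69 ± 0.29 (3.22-fold, adjusted p = 0.011). Coq10b, which encodes a coenzyme Q binding protein of mitochondria, rose by 1.14 ± 0.21 (2.21-fold, adjusted p = 0.0163). Insig2, which holds SREBP precursors in the endoplasmic reticulum, fell by 0.93 ± 0.18 (adjusted p = 0.0163), 1.90-fold lower. For Ciart, Usp2 and Coq10b all 8 HC+EZE arrays lay above the highest HC array, and for Insig2 all 8 lay below the lowest. The other probes of Ciart, Coq10b and Insig2 moved the same way, while the 2 dim other probes of Usp2, detected on 10 and 9 arrays, differed by 0.18 ± 0.10 and 0.29 ± 0.12.

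Of the 12 measured circadian clock genes 0 passed over all genes tested, while 4 were higher and 2 lower when adjusted over the list alone. Per1, a light- and feeding-responsive repressor of the clock, differed by 0.94 ± 0.21 (adjusted p over the list alone = 0.00137, over all genes 0.134), and Dbp, an output transcription factor that peaks late in the day, by 0.98 ± 0.33. The core activators Arntl and Clock differed by -0.82 ± 0.21 and -0.57 ± 0.16. Arntl was near background: its probe was detected on 8 of 8 HC, 5 of 8 HC+RSV, 2 of 8 HC+EZE and 2 of 8 HC+RSV+EZE arrays, so its differences are not exact sizes. As a group these 12 genes had a mean difference of 0.24 and did not pass (camera, adjusted p = 0.0869), with 10 members above 0 and 2 below; blocking on chip it had an adjusted p of 0.0317. The clock list's adjusted p = 0.845 with an estimated correlation, and it was 0.0775 without the 4 arrays that stood apart. Genes of bile acid synthesis and transport had a mean difference of -0.16 (camera, adjusted p = 0.0869), with 12 of 14 members below 0, and an adjusted p of 0.0317 with chip as a block. The bile acid list's adjusted p = 0.845 with an estimated correlation, and it was 0.424 without the 4 arrays that stood apart. Among them Cyp8b1, the enzyme that makes cholic acid, differed by -0.75 ± 0.25 (adjusted p = 0.876). The mean difference of cholesterol synthesis genes was 0.14 (adjusted p = 0.278).

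**Figure D2:**
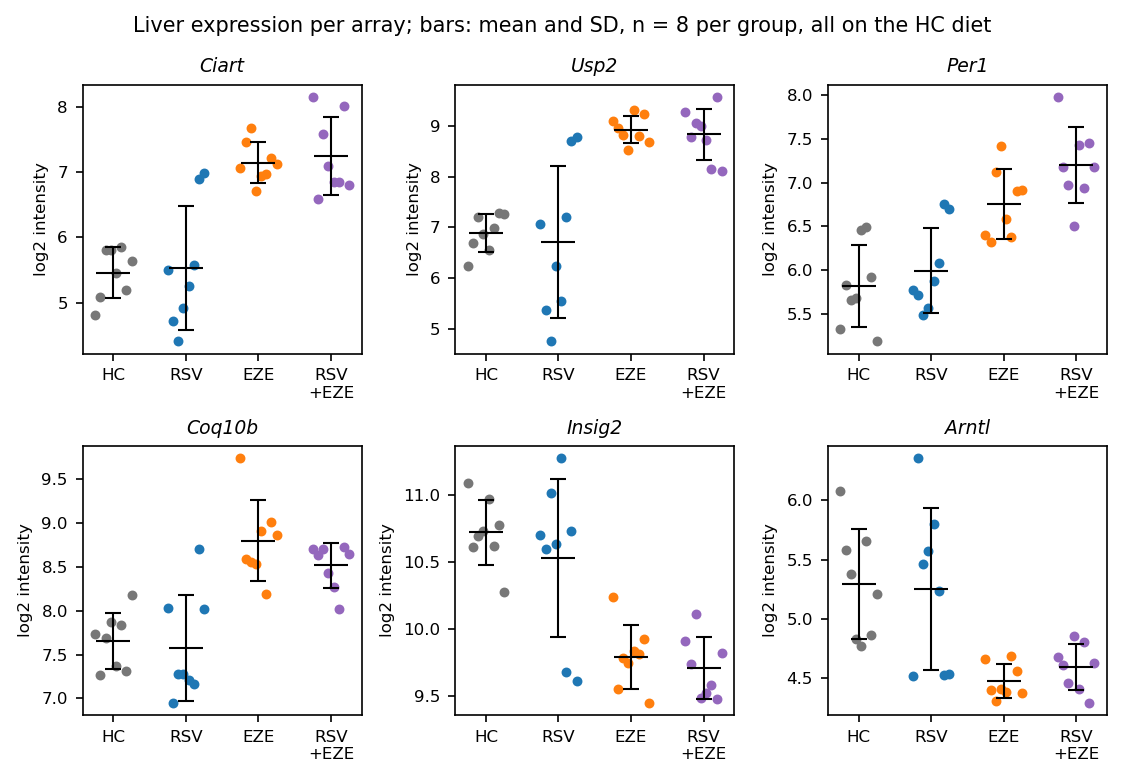
Log2 intensity (y axis) of Ciart, Usp2, Per1, Coq10b, Insig2 and Arntl in each liver by group (x axis), where points are arrays set side by side by replicate number and bars give the mean and SD of 8. Ciart ranges from 4.82 to 5.85 in HC, 4.41 to 6.99 in HC+RSV, 6.71 to 7.68 in HC+EZE and 6.59 to 8.16 in HC+RSV+EZE, and Insig2 runs the opposite way.

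The sterol genes fixed in advance did not pass in this comparison. Sqle differed by 0.40 ± 0.50, Insig1 by 0.26 ± 0.34, Srebf2 by 0.09 ± 0.16 and Srebf1 by 0.36 ± 0.27. Cyp7a1 differed by -0.08 ± 0.27, Abcg5 by 0.02 ± 0.19, Abca1 by -0.05 ± 0.12 and Saa1 by 0.31 ± 0.42. The signs of Srebf2, Cyp7a1, Abcg5 and Saa1 turned under some settings (Srebf2 and Abcg5 with equal medians, -0.044 and -0.086, Cyp7a1 with array weights, 0.088, and Saa1 with the authors' values, -0.21).

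No gene list passed between HC+EZE and HC, where camera's smallest adjusted p was 0.0869 and with chip as a block 5 lists passed, the clock and bile acid lists among them. The genes past the threshold numbered 4 (322 at an unadjusted p under 0.05), and with chip as a block all 4 passed again, as the whole count of that fit. On each of the 6 chips Ciart was higher with ezetimibe, by 0.86 to 2.23, and Insig2 was lower, with differences of -1.23 to -0.61. The count was 0 with the authors' normalized values (337 at an unadjusted p under 0.05), where Usp2, Ciart and Coq10b differed by 2.22, 2.22 and 1.22, no less than in the fit reported here. It was also 0 with array position as a covariate (1047), where the difference of Ciart went from 1.69 ± 0.29 to 0.26 ± 1.16. The larger standard error follows from position and ezetimibe nearly coinciding, and the cause of the lower estimate was not tested. Without HC replicate 1 Usp2 and Insig2 were lost, leaving 2 genes, and without HC replicate 5 the count was 8.

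The comparison of HC+RSV+EZE with HC asked what the 2 drugs did together. As with ezetimibe alone, Ciart and Usp2 rose and Insig2 fell. Per1 rose by 1.38 ± 0.21 (2.61-fold, limma, adjusted p = 0.00208), Ciart by 1.78 ± 0.29 (3.44-fold, adjusted p = 0.00208) and Usp2 by 1.94 ± 0.38 (3.84-fold, adjusted p = 0.029). Insig2 fell by 1.02 ± 0.18 (2.02-fold lower, adjusted p = 0.00498). All 8 HC+RSV+EZE arrays lay above the highest HC array for Per1, Ciart and Usp2, and below the lowest for Insig2. Among the 12 clock genes 1 was higher and 0 lower over all genes tested, and adjusted over the list alone 3 were higher and 2 lower. The members that passed only over the list alone included Dbp (0.95 ± 0.33), Arntl (-0.70 ± 0.21, detected on 2 of 8 HC+RSV+EZE arrays) and Clock (-0.67 ± 0.16). As a group the 12 genes had a mean difference of 0.21, with 4 members below 0, and did not pass (camera, adjusted p = 0.241).

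Genes of bile acid synthesis and transport were lower as a group, with a mean of -0.27 and 12 of 14 members below 0 (camera, adjusted p = 0.00176); with an estimated correlation the adjusted p = 0.953. None passed over all genes tested, and 2 were lower adjusted over the list alone: Cyp8b1 (-0.85 ± 0.25) and Hsd3b7 (-0.53 ± 0.15), an early enzyme of bile acid synthesis. Genes of oxidative phosphorylation were higher as a group, with a mean of 0.26 and 19 of 22 members above 0 (camera, adjusted p = 0.00176); with an estimated correlation the adjusted p = 0.953. None of the 22 passed singly, over all genes or adjusted over the list alone. Cox7b, a subunit of cytochrome oxidase, differed by 0.53 ± 0.28 and Ndufb5, a subunit of complex I, by 0.51 ± 0.22. The 4 arrays that stood apart were low in oxidative phosphorylation genes and high in bile acid genes, and HC held 2 of them and HC+RSV+EZE none. A block for chip gave an adjusted p of 0.00137 for bile acid and 0.0274 for oxidative phosphorylation genes, the latter higher on 3 of the 6 chips. Without the 4 arrays the mean difference was -0.03 for oxidative phosphorylation (adjusted p = 0.626) and -0.13 for bile acid genes (adjusted p = 0.225).

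Genes of cholesterol synthesis were higher as a group, with a mean of 0.30 and 13 of 15 members above 0 (camera, adjusted p = 0.0279). With an estimated correlation the adjusted p = 0.953, and with chip as a block it was 0.61, with the list higher on 2 and lower on 4 of the 6 chips (-0.86 to 0.54). It was 0.332 without the 4 arrays that stood apart. None of the 15 passed over all genes or adjusted over the list alone. Lss differed by 0.65 ± 0.30, Fdps, which makes farnesyl diphosphate, by 0.54 ± 0.40 and Sqle by 0.57 ± 0.50 (limma, adjusted p = 0.782). Blocking on chip, Lss, Fdps and Sqle differed by 0.42, 0.17 and 0.062, and without HC+RSV+EZE replicate 7 Sqle differed by 0.27. Tmem97, a sterol-regulated gene from the list of other SREBP-2 targets, differed by 0.53 ± 0.17 and Cyp3a11, a xenobiotic-metabolizing cytochrome, by -0.69 ± 0.19. Each of these was the 1 member of its list that passed adjusted over the list alone, with 0 over all genes. Insig1 differed by -0.04 ± 0.34, Srebf2 by 0.23 ± 0.16, Srebf1 by 0.07 ± 0.27, Cyp7a1 by -0.40 ± 0.27, Abcg5 by -0.09 ± 0.19, Abca1 by 0.07 ± 0.12 and Saa1 by 0.12 ± 0.42, and none passed. The signs of Insig1, Srebf1, Abcg5 and Abca1 turned under other scalings, weights or sets of arrays (Srebf1 -0.22 and Abca1 -0.057 with equal medians, Insig1 0.002 with cyclic loess and Abcg5 0.062 with array weights).

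**Figure D3:**
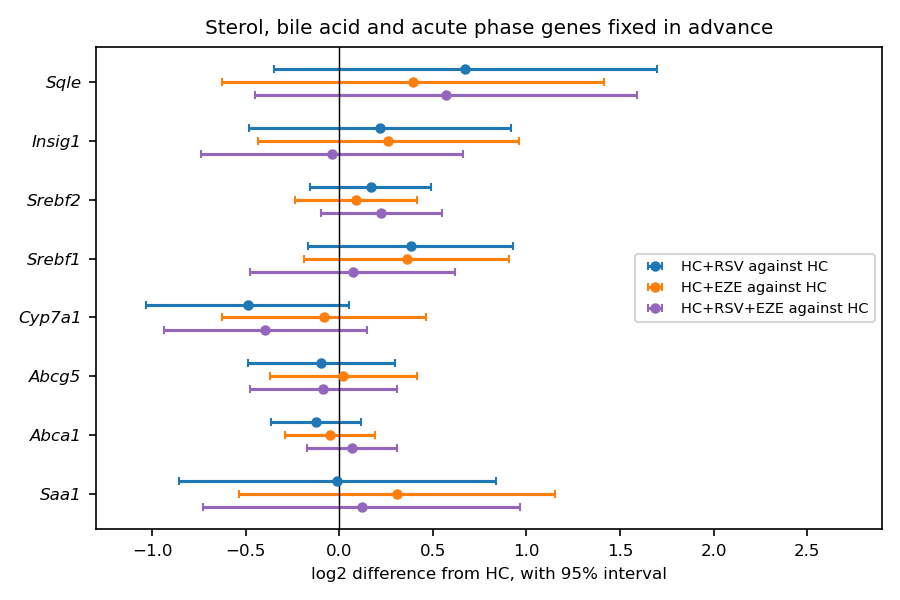
Log2 difference from HC (x axis) with its 95% interval from the limma fit for 8 genes of sterol, bile acid and acute phase biology (y axis), in HC+RSV, HC+EZE and HC+RSV+EZE (8 livers each). Every interval includes 0; the widest are those of Sqle, -0.35 to 1.70 in HC+RSV.

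In all, 3 genes rose and 1 fell between HC+RSV+EZE and HC (658 at an unadjusted p under 0.05), and with chip as a block 3 rose and 7 fell, the 4 of the unblocked fit among them. The blocked fit added Tmie (-1.17 ± 0.19), Pnkd (-1.09 ± 0.19), Ddc (-1.07 ± 0.22) and Gm4952 (-1.02 ± 0.21) to the genes with the largest falls. Ciart was higher on each of the 6 chips, by 0.85 to 2.62, and Insig2 lower, from -1.28 to -0.82. With the authors' normalized values 2 genes passed and with array position as a covariate 0 (1069 at an unadjusted p under 0.05). Single arrays moved the count to 7 (without HC replicate 3, or 5), 9 (without HC+RSV replicate 3, HC+RSV replicate 8 or HC+RSV+EZE replicate 2) and 10 (without HC replicate 6), and the oxidative phosphorylation call was lost without HC replicate 1 (adjusted p = 0.154) or 8, the cholesterol synthesis call in 8 of 32 fits (highest adjusted p = 0.376, without HC+RSV+EZE replicate 7) and that of Usp2 in 8 of 32 (0.0999, without HC replicate 1).

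**Figure D4:**
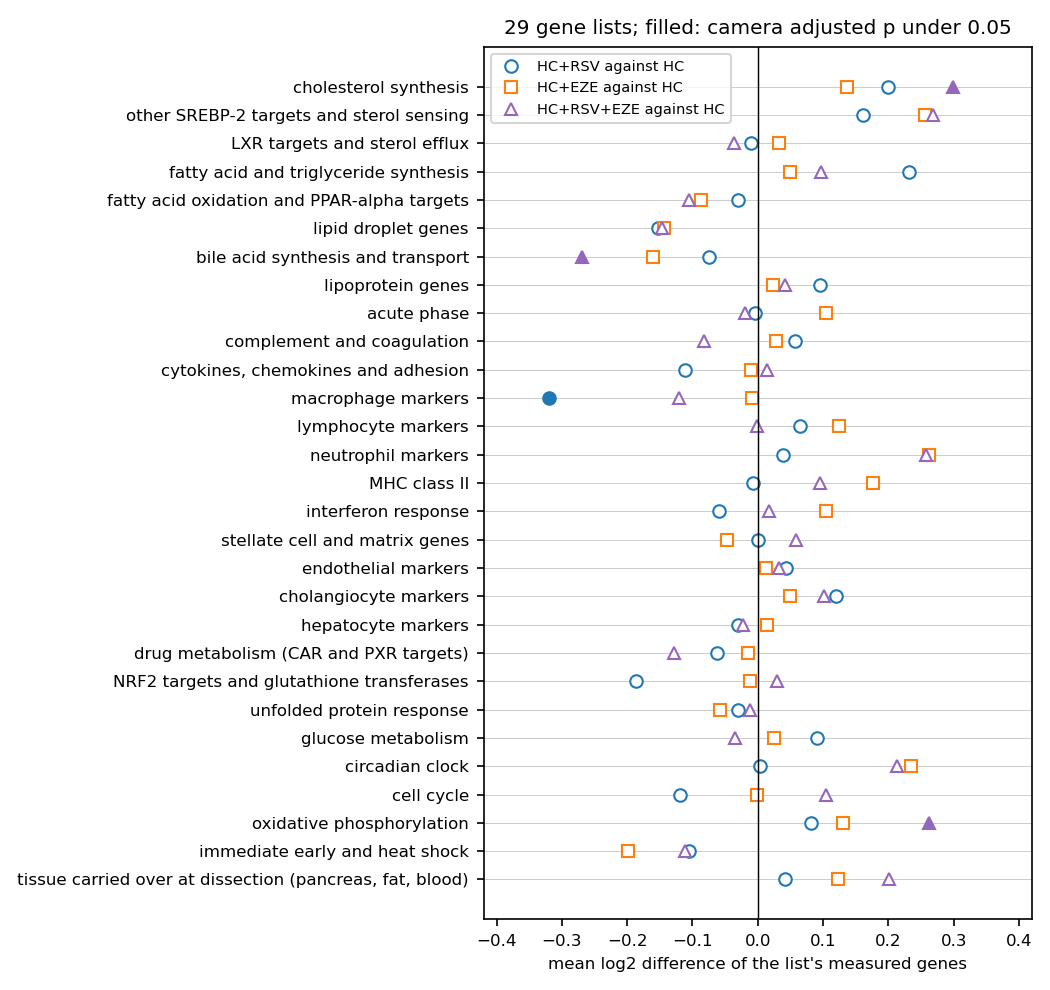
Mean log2 difference from HC (x axis) of the measured genes of 29 gene lists (y axis) in HC+RSV, HC+EZE and HC+RSV+EZE; filled symbols passed camera's test at an adjusted p under 0.05 with its preset correlation. Filled symbols are macrophage markers in HC+RSV (-0.32) and bile acid (-0.27), oxidative phosphorylation (0.26) and cholesterol synthesis genes (0.30) in HC+RSV+EZE.

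The comparison of HC+RSV+EZE with HC+RSV asked what ezetimibe added to the statin. Here 4 genes rose and 1 fell. Usp2 rose by 2.12 ± 0.38 (4.34-fold, limma, adjusted p = 0.00985), Ciart by 1.71 ± 0.29 (3.26-fold, adjusted p = 0.00917) and Per1 by 1.21 ± 0.21 (2.31-fold, adjusted p = 0.00985). Ifitm1, an interferon-induced membrane protein gene, rose by 0.76 ± 0.14 (1.70-fold, adjusted p = 0.0138). Pnkd, named for a paroxysmal movement disorder, fell by 1.03 ± 0.21 (2.04-fold lower, adjusted p = 0.047). The spread within HC+RSV was wide: Usp2 stood at 6.71 ± 1.5 (SD, n = 8) there, against 8.83 ± 0.51 in HC+RSV+EZE, and 2 of the 8 HC+RSV arrays lay above the highest HC array for Ciart and for Usp2.

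Among the 12 clock genes 1 was higher over all genes tested, and adjusted over the list alone 3 were higher and 2 lower, with Arntl at -0.66 ± 0.21 (detected on 5 of 8 HC+RSV and 2 of 8 HC+RSV+EZE arrays) and Clock at -0.59 ± 0.16. As a group these genes did not pass (mean 0.21, camera, adjusted p = 0.257). Genes of the cell cycle were higher as a group, with a mean of 0.22 and 12 of 13 members above 0 (camera, adjusted p = 0.0281); with an estimated correlation the adjusted p = 0.969. Pcna, the replication clamp, detected on 5 of 8 HC+RSV and 8 of 8 HC+RSV+EZE arrays, differed by 0.50 ± 0.14 and Mcm6, a subunit of the replicative helicase, by 0.54 ± 0.29. Adjusted over the list alone 1 member, Pcna, was higher, with 0 over all genes. Genes of bile acid synthesis and transport were lower, with a mean of -0.20 (camera, adjusted p = 0.0475); with an estimated correlation the adjusted p = 0.969. Cyp8b1 differed by -0.74 ± 0.25 and Hsd3b7 by -0.48 ± 0.15, the 2 members lower adjusted over the list alone, with 0 over all genes. Genes of oxidative phosphorylation were higher, with a mean of 0.18 (camera, adjusted p = 0.0475); with an estimated correlation the adjusted p = 0.969. Blocking on chip, the adjusted p was 0.0044 for cell cycle, 0.031 for bile acid and 0.07 for oxidative phosphorylation genes, and 2 further lists passed, NRF2 targets and glutathione transferases higher (0.0156) and complement and coagulation lower (0.031). With an estimated correlation, in the fit without the block, no list passed in this comparison (camera, smallest adjusted p = 0.969). HC+RSV holds 1 of the 4 arrays that stood apart, and without them 0 lists passed in this comparison, with adjusted p of 0.0946 for cell cycle, 0.149 for bile acid and 0.0946 for oxidative phosphorylation genes.

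With chip as a block 29 genes rose and 18 fell between HC+RSV+EZE and HC+RSV, the 5 of the unblocked fit among them; the unblocked fit had 649 genes at an unadjusted p under 0.05. In the blocked fit Coq10b rose by 0.998 ± 0.20 and Pcsk4 by 0.93 ± 0.20. Gldc, of glycine cleavage, fell by 1.02 ± 0.22, and Tmie by 1.03 ± 0.19, Clpx by 0.99 ± 0.23 and Cldn1, of tight junctions, by 0.99 ± 0.22. With only the 16 arrays of these groups in the fit the count was 0 (limma, 621 at an unadjusted p under 0.05), and with array position as a covariate it was 0 (936). Single arrays moved the count to 3 (without HC+RSV replicate 3, where the bile acid and oxidative phosphorylation adjusted p were 0.248 and 0.295), 8 (without HC+RSV replicate 6, or HC+EZE replicate 1) and 18 (without HC+RSV replicate 8), Ifitm1 was lost without HC+RSV replicate 3 (adjusted p = 0.0508), Pnkd in 21 of 32 fits that each left out 1 array, and the cell cycle call in 6 (highest adjusted p = 0.122, without HC+RSV+EZE replicate 8). The bile acid call was lost in 13 of these 32 fits and the oxidative phosphorylation call in 15.

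The comparison of HC+RSV+EZE with HC+EZE asked what the statin added to ezetimibe. limma called 0 genes, with 151 (1.71%) at an unadjusted p under 0.05, and 0 with chip as a block, with 283. No list passed (camera, smallest adjusted p = 0.0818). Genes of complement and coagulation had a mean difference of -0.11, with 20 of 22 members below 0, and those of cholesterol synthesis 0.16, with 14 of 15 above 0, both at an adjusted p of 0.0818. A block for chip turned the direction of cholesterol synthesis (adjusted p = 0.936), and that list was higher on 3 and lower on 3 of the 6 chips. Blocking on chip, 4 lists passed, complement and coagulation among them (adjusted p = 0.00918). That list's adjusted p = 0.911 with an estimated correlation, it was 0.108 without the 4 arrays that stood apart, and 0 lists passed without them.

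The comparison of HC+EZE with HC+RSV set the 2 single drugs against each other. Usp2 was higher with ezetimibe by 2.21 ± 0.38 (4.63-fold, limma, adjusted p = 0.007), Ciart by 1.61 ± 0.29 (3.06-fold, adjusted p = 0.00813) and Coq10b by 1.22 ± 0.21 (2.33-fold, adjusted p = 0.007). These standard errors rest on 1 spread shared by all 4 groups, though the groups differed in spread. Usp2 had an SD of 1.5 in HC+RSV and 0.27 in HC+EZE, and Ciart of 0.95 and 0.31. Macrophage markers were higher as a group, with all 13 members above 0 and a mean of 0.31 (camera, adjusted p = 0.0102); with an estimated correlation the adjusted p = 0.907. Vsig4 differed by 0.33 ± 0.20 and Lyz2, lysozyme of myeloid cells, by 0.36 ± 0.32, and none of the 13 passed over all genes or adjusted over the list alone. Without HC+RSV replicate 3 Lyz2 differed by 0.10. The list's adjusted p with chip as a block was 0.0018, and without the 4 arrays that stood apart it was 0.15. Among the clock genes 0 passed over all genes, and adjusted over the list alone 5 were higher and 2 lower. In all 3 genes were higher and 0 lower (399 at an unadjusted p under 0.05). With chip as a block 4 were higher and 2 lower, the 3 above among them, and Nampt, the rate-limiting enzyme of NAD salvage (0.78 ± 0.16), Gtf3c1 (-0.76 ± 0.14) and Insig2 (-0.74 ± 0.15) joined. The count was 0 with only the 16 arrays of these groups in the fit (359 at an unadjusted p under 0.05), 0 with equal medians (289) and 0 with array position as a covariate (859). Without HC+RSV replicate 8 it was 9, and the macrophage call was lost without HC+RSV replicate 1 (adjusted p = 0.229), HC+RSV replicate 3 or HC+EZE replicate 4.

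The interaction asked whether the 2 drugs together differed from the sum of the single drugs. limma called 0 genes (152 at an unadjusted p under 0.05, and 0 with chip as a block, with 348), and the median standard error of an interaction was 0.22. Genes of complement and coagulation had a mean interaction of -0.17, with 19 of 22 members below 0 (camera, adjusted p = 0.0163); with an estimated correlation the adjusted p = 0.992. C4b, a complement component, had an interaction of -0.45 ± 0.29 and F7, a coagulation factor, of -0.40 ± 0.30. Genes of the cell cycle had a mean interaction of 0.22, with 12 of 13 members above 0 (camera, adjusted p = 0.0163); with an estimated correlation the adjusted p = 0.992. Pcna had an interaction of 0.45 ± 0.19 and Mcm6 of 0.40 ± 0.41, and no member of either list passed over all genes or adjusted over the list alone. The adjusted p with chip as a block was 0.000608 for complement and coagulation and 0.00446 for cell cycle genes, and without the 4 arrays that stood apart 0.00579 and 0.143. Leaving out single arrays ended the complement call in 9 of 32 fits (highest adjusted p = 0.171, without HC replicate 6) and the cell cycle call in 12 of 32 (0.13, without HC+RSV replicate 1).

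The 3 comparisons with HC share its 8 arrays, so their differences correlate without any drug effect. Across the 8853 genes, which are not independent replicates, the differences in HC+EZE and HC+RSV+EZE correlated at 0.766, against 0.5 for simulated unchanged groups, with a covariance of 0.0286 against 0.0181. All simulated values of this paragraph treat arrays and genes as independent and leave out chip, though arrays of the same chip correlated at 0.295 on average across groups. The 2 shared 3 called genes, Ciart and Usp2 higher and Insig2 lower. Simulated unchanged groups shared 0, and independent lists would share 0.00102 higher and 0.000113 lower. Neither value tests a common effect, since the simulated groups held no changed gene and independent lists would not share the HC arrays. With the HC arrays split 4 and 4 between the 2 comparisons the correlation averaged 0.162 over 70 splits, from -0.294 to 0.503. For HC+RSV and HC+EZE the correlation was 0.405 against 0.5 simulated, the covariance 0.0103 against 0.0181, and the split value -0.197. For HC+RSV and HC+RSV+EZE it was 0.401 against 0.5, the covariance 0.0128 against 0.0181, and the split value -0.111. The single drugs shared 0 called genes, as HC+RSV had 0 (limma, 235 at an unadjusted p under 0.05).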

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

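The test of chip differences for Ciart, Usp2, Coq10b, Per1 and Insig2, and leaving out the 4 arrays that stood apart as a setting, were chosen only after the result was seen. The direction of the clock list and the correlation of the lists with the first principal component were also known when the tests of clock phase, of the 4 arrays and of that component were set, so these are not blind tests. Dixon's ratio was computed for 72 groups of 8 livers and 8 exceeded its critical value, where chance flags about 1 in 20 groups, here 3.6. HC+RSV replicate 6 had 13444 detected probes where the others had 10765 to 11982 (ratio 0.546). The mean correlation of HC+RSV replicate 3 with the other arrays was 0.926 where the others of its group had 0.963 to 0.973 (0.787), and that of HC+EZE replicate 1 was 0.951 where the others had 0.970 to 0.973 (0.86). Cyp7a1 stood at 12.25 in HC+EZE replicate 5 and at 11.20 or less in the others (0.616). Abca1 stood at 4.76 in HC replicate 3 and at 5.10 or more in the others (0.583). Saa1 stood at 5.75 in HC replicate 7 against 4.90 or less (0.568), and at 9.02 in HC+EZE replicate 5 against 4.63 or less (0.915). Pnkd stood at 7.35 in HC+RSV+EZE replicate 4 against 7.78 or more (0.529). As lists, complement and coagulation genes had a mean interaction of -0.168 and cell cycle genes of 0.223. Camera's adjusted p was 0.0163 for both and 0.992 with an estimated correlation. The 2 calls were lost in 9 and 12 of 32 fits that each left out 1 array, and that of the cell cycle also without the 4 arrays. No single gene had a called interaction, so whether the drug effects added up is not settled.

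Ciart, Usp2, Coq10b and Per1 were higher and Insig2 lower in livers with ezetimibe, while the 12 listed clock genes did not pass as a group (camera, adjusted p = 0.0911, 0.921 with an estimated correlation and 0.06 with chip as a block), though without the 4 arrays that stood apart they passed (0.0311). Camera was run for a shift of the list as a whole in the same direction, and members of this list moved both ways. A difference between chips as the whole cause is argued against, since the genes called against HC passed again with chip as a block; that the score of these 5 genes was higher with ezetimibe on 6 of 6 chips adds little, as they were chosen for that difference. Evening minus morning clock genes outside the score differed by 0.928 between livers with and without ezetimibe (permutation p = 4e-04, 16 against 16), by 0.61 without and 1.246 with rosuvastatin. Between HC+RSV and HC this measure differed by -0.367. The evening genes alone differed by 0.422, from 0.004 (Hlf) to 1.069 (Dbp), with Hlf and Wee1 near background. The 1 morning gene of this test, Nfil3, differed by -0.506, but by only -0.15 ± 0.24 with ezetimibe alone. Nr1d1, a clock gene outside this test, differed by 0.035 ± 0.19 in HC+EZE against HC. Another phase of the clock may account for the pattern, but the measure rests largely on Nfil3 and the labels give no sampling time. Array position cannot be told apart from ezetimibe: the score's slope per position within groups was 0.455 (95% interval -0.066 to 0.976), where 0.447 would be needed, and it was 0.312 within HC, 1.436 within HC+RSV, 0.016 within HC+EZE and -0.124 within HC+RSV+EZE. A direct effect of ezetimibe stays open and was not tested.

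Oxidative phosphorylation genes were higher and bile acid genes lower with both drugs than on HC. A difference between chips as the whole cause is argued against by the fit with chip as a block. There camera's probability before adjustment was 0.00189 for the first list (adjusted p = 0.0274) and 4.73e-05 for the second (adjusted p = 0.00137). The first list was higher on some chips only, so for it this speaks only against a level shared by all arrays of a chip. Without the 4 arrays that stood apart the oxidative phosphorylation shift was -0.027 in place of 0.263, and with the first principal component as a covariate 0.078. The bile acid shift was -0.126 and -0.114 in place of -0.269, so variation between arrays unrelated to group may account for the first list and for part of the bile acid list. Array position cannot be told apart from the drugs here, as HC arrays lay at A and B and HC+RSV+EZE arrays at G and H. With position as a covariate Cyp8b1 and Hsd3b7 turned to 1.11 and 1.35, while Cyp7a1 stood at -0.86. Ndufb5 turned to -0.13, while Cox7b stood at 0.83. An effect of the drugs on bile acid genes stays open and was not tested.

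Macrophage markers were lower on HC+RSV than on HC. The first principal component is argued against as the cause, since with it as a covariate the shift was -0.312 in place of -0.319, and so is a difference between chips, where camera's probability before adjustment was 0.000219 with chip as a block (adjusted p = 0.00636). Without the 4 arrays the shift was -0.178 (camera, adjusted p = 0.0501), which leaves open whether these arrays could account for part of it. Array position was not weighed for this list, and HC+RSV arrays lay at B and C where HC arrays lay at A and B. Fewer macrophages with rosuvastatin, or lower expression in them, stays open and was not tested.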

How the results depend on the processing

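Leaving out the 4 arrays of lowest mean correlation, alone or with chip as a block, chip as a block with array weights, and the comparisons averaged over the other drug were chosen only after the result was seen. For the 16 called gene differences, 697 of 768 values under the alternatives kept the direction and the side of the threshold, 64 kept the direction only and 7 turned. For 70 differences not called, 3147 of 3352 kept both, 123 passed the threshold and 82 turned. In HC+RSV against HC, HC+RSV+EZE against HC+EZE, the interaction and the calls shared by the single drugs the count was 0 under every alternative run (limma; 235, 151 and 152 genes at an unadjusted p under 0.05 in the 3 comparisons). Scaling to equal medians moved the median of all genes by -0.114 (HC+EZE against HC), -0.177 (HC+RSV+EZE against HC) and -0.133 (HC+RSV+EZE against HC+RSV), and changes are relative to it. Signal near background limits dim probes. Except where stated, the cause was not tested.

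Counts that moved are given in the order HC+EZE against HC, HC+RSV+EZE against HC, HC+RSV+EZE against HC+RSV, HC+EZE against HC+RSV, where 4, 4, 5 and 3 genes passed, with 10 gene lists. With equal medians they were 2 (1 higher, 1 lower), 9 (2 and 7), 6 (1 and 5) and 0 (289 at an unadjusted p under 0.05), with 25 lists. With cyclic loess 11 genes passed in HC+RSV+EZE against HC+RSV (6 and 5). With the authors' values 0 (337 at an unadjusted p under 0.05) and 2 passed in the comparisons with HC, with 5 lists. Over every kept probe 8, 11 and 7 probes passed in the last 3. With chip as a block 10, 47 and 6 genes passed there, with 25 lists and 89 genes for livers with EZE against livers without. A random chip block gave 17, 33 and 8. With array position as a covariate 0 passed in all 4 (1047, 1069, 936 and 859 at an unadjusted p under 0.05), with 72 lists, and standard errors of the called genes grew 3.03 to 5.08 times, as position nearly coincides with ezetimibe. With array weights 8, 14 and 11 passed in the last 3. Without the 4 arrays 9, 13 and 5 passed there, with 3 lists. Without them and with chip as a block 10, 14, 118 and 19 passed, with 22 lists. With chip as a block and array weights 38, 56, 94 and 47 passed, with 18 lists. With only the groups compared 7, 9, 0 (621 at an unadjusted p under 0.05) and 0 (359) passed. With an estimated correlation 0 lists passed. The fits with a chip block, array weights or without all 4 arrays shared all 4, 4, 5 and 3 genes of the fit reported.

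With the replicate block 8, 9 and 16 genes passed in the first 3 comparisons, with 17 lists. Same-numbered HC+RSV and HC+EZE arrays lay on the same chip in all 8 pairs, and those of the other groups did not. The 48 pairs of arrays with the same number correlated at 0.175 on average, from -0.235 to 0.762, 30 of them over 0.1, against -0.019 and 124 of 336 for different numbers, so the numbers were not taken to pair the samples across the 4 groups; 7 of 32 arrays correlated best with their own number.

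Leaving out 1 array gave 2 to 8 genes in HC+EZE against HC (without HC replicate 1 and HC replicate 5), 3 to 10 in HC+RSV+EZE against HC (without HC replicate 1 and 6), 3 to 18 in HC+RSV+EZE against HC+RSV (without HC+RSV replicate 3 and 8), 3 to 9 in HC+EZE against HC+RSV (highest without HC+RSV replicate 8), and 4 to 24 lists. The lists numbered 4 without HC+RSV+EZE replicate 2, 6 without HC+RSV replicate 1, HC+RSV replicate 3, HC+EZE replicate 5 or HC+RSV+EZE replicate 8, 16 without HC replicate 3, HC+RSV replicate 6 or HC+EZE replicate 6, 20 without HC+RSV replicate 5, 21 and 23 without HC+RSV+EZE replicate 7 and 1, and 24 without HC replicate 5. Insig2 in HC+EZE against HC was also lost without HC+EZE replicate 2 or 8 (highest adjusted p = 0.0662). Differences that turned ranged, for HC+RSV against HC, from -0.18 to 0.009 (Abcg5) and -0.084 to 0.15 (Saa1). For HC+EZE against HC the ranges were -0.25 to 0.01 (Cyp7a1), -0.11 to 0.13 (Abcg5), -0.11 to 0.038 (Abca1) and -0.27 to 0.47 (Saa1). For HC+RSV+EZE against HC they were -0.25 to 0.15 (Insig1), -0.08 to 0.23 (Srebf1) and -0.17 to 0.02 (Abcg5).

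With equal medians, the turned differences were Srebf2 -0.044 and Abcg5 -0.086 (HC+EZE against HC), Srebf1 -0.22 and Abca1 -0.057 (HC+RSV+EZE against HC). With cyclic loess, the turned differences were Insig1 0.002 (HC+RSV+EZE against HC). With the authors' values, the turned differences were Saa1 0.11 (HC+RSV against HC), Saa1 -0.21 (HC+EZE against HC). Blocking on chip, the turned differences were Saa1 0.17 (HC+RSV against HC), Abcg5 0.007 (HC+RSV+EZE against HC). Under a random chip block, the turned differences were Saa1 0.083 (HC+RSV against HC). With position as a covariate, HC+EZE against HC, the turned differences were Abcg5 -0.97, Saa1 -3.08, Usp2 -1.02, Insig2 0.27, Arntl 0.24, Clock 1.33, Dbp -0.93 and Cyp8b1 0.83. For HC+RSV+EZE against HC the position covariate gave Insig1 3.01, Abca1 -0.17, Saa1 -4.08, Usp2 -1.84, Insig2 0.47, Tmie 1.498, Pnkd 1.69, Gm4952 2.37, Cyp8b1 1.11, Hsd3b7 1.35, Ndufb5 -0.13, Arntl 0.61, Clock 1.69 and Dbp -1.42. With position as a covariate, HC+RSV+EZE against HC+RSV, the turned differences were Usp2 -0.94, Pnkd 1.12, Tmie 1.09, Gldc 1.20, Clpx 0.61, Cldn1 0.38, Pcna -0.72, Mcm6 -1.90, Cyp8b1 0.84, Hsd3b7 1.05, Arntl 0.41 and Clock 1.32. For HC+EZE against HC+RSV the position covariate gave Usp2 -0.12, Insig2 0.18, Vsig4 -0.82 and Lyz2 -1.78. With array weights, the turned differences were Insig1 -0.001 and Saa1 0.004 (HC+RSV against HC), Cyp7a1 0.088 (HC+EZE against HC), Srebf1 -0.086 and Abcg5 0.062 (HC+RSV+EZE against HC). Without the 4 arrays, the turned differences were Abcg5 0.055 (HC+RSV against HC), Cyp7a1 0.15 (HC+EZE against HC), Srebf1 -0.073 and Abcg5 0.12 (HC+RSV+EZE against HC). Without the 4 arrays and with chip as a block, the turned differences were Cyp7a1 0.12 (HC+EZE against HC), Srebf1 -0.054 and Abcg5 0.18 (HC+RSV+EZE against HC). Under a chip block and array weights, the turned differences were Saa1 0.009 (HC+RSV against HC), Cyp7a1 0.006 (HC+EZE against HC), Srebf1 -0.004 and Abcg5 0.19 (HC+RSV+EZE against HC).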

Other observations

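The comparisons averaged over the other drug, their splits and leaving out the 4 arrays were chosen only after the result was seen. Planned were the counts over other splits of the samples for the 6 pairwise comparisons and over shuffled residuals for the interaction. Comparing the 16 livers with ezetimibe with the 16 without, 12 genes rose and 18 fell (limma, 836 at an unadjusted p under 0.05). Besides Usp2 (2.08 ± 0.27, adjusted p = 2.7e-05), Ciart (1.70 ± 0.20, 8.56e-06), Per1 (1.07 ± 0.15, 6.91e-05) and Coq10b (1.04 ± 0.15, 6.91e-05), the clock output gene Dbp rose by 1.07 ± 0.23 (adjusted p = 0.0201). The core activators Arntl and Clock fell by 0.74 ± 0.14 (adjusted p = 0.00618) and 0.58 ± 0.11 (0.00567), where Arntl was detected on 2 of 8 HC+EZE and 2 of 8 HC+RSV+EZE arrays, so that the size of its fall is not exact. Nampt, of NAD salvage, rose by 0.67 ± 0.13 (0.00381) and Nmrk1, a nicotinamide riboside kinase, by 0.73 ± 0.13 (0.00304). Gldc, of glycine cleavage, fell by 0.92 ± 0.17 (0.00299), Ddc, aromatic amino acid decarboxylase, by 0.87 ± 0.16 (0.00328), Clpx, a mitochondrial unfoldase, by 0.97 ± 0.17 (0.00216), Pnkd by 0.90 ± 0.15 (0.00122) and Insig2 by 0.88 ± 0.12 (6.91e-05). Each of these 14 genes went the same way on 6 of 6 chips, which adds little, as they were chosen for that difference. Dbp had an adjusted p of 0.0711 without the 4 arrays that stood apart. Array position nearly coincides with ezetimibe here too, and this averaged comparison was not fitted with position as a covariate. Arntl, Clock, Nampt and Nmrk1 were named after their values were seen. With chip as a block 89 genes passed, 38 higher and 51 lower, all 30 among them, and without the 4 arrays 26, of which 23 were shared.

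Among the 12 clock genes 2 were higher and 2 lower over all genes, and 4 higher and 2 lower adjusted over the list alone. As a group they did not pass (camera, adjusted p = 0.0911, 0.921 with an estimated correlation, 0.06 with chip as a block) and had 0.0311 without the 4 arrays. Bile acid genes were lower with ezetimibe as a group (mean -0.18, camera, adjusted p = 0.021) and oxidative phosphorylation genes higher (0.16, 0.021); with an estimated correlation both had an adjusted p = 0.921, with chip as a block they had 0.0211 and 0.06, and without the 4 arrays 0.226 and 0.724. Comparing the 16 livers with rosuvastatin with the 16 without, limma called 0 genes (209 at an unadjusted p under 0.05). Macrophage markers were lower as a group (mean -0.22, camera, adjusted p = 0.001) and cholesterol synthesis genes higher (0.18, 0.0191). With an estimated correlation both had an adjusted p = 0.835, with chip as a block they had 0.0138 and 0.381, and without the 4 arrays 0.00418 and 0.889. Of the 2 comparisons averaged here, the macrophage list passed in HC+RSV against HC (mean -0.319). In HC+RSV+EZE against HC+EZE no list passed (camera, smallest adjusted p = 0.0818), so the average is no repeat of the macrophage shift with ezetimibe present.

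Other splits of the samples into groups of the same sizes, 100 including the real one, gave as many genes in 3 splits for HC+EZE against HC (4 real, highest other 117), in 2 for HC+RSV+EZE against HC (4, highest other 221), in 2 for HC+RSV+EZE against HC+RSV (5, highest other 11), in 1 for HC+EZE against HC+RSV (3, highest other 0) and in 2 for livers with ezetimibe against livers without (30, highest other 66). Each of these shares taken singly lies under 0.05. They were not adjusted for the number of comparisons, which share arrays, and the splits took no account of chip, so chance is not excluded. In 4 of these 5 comparisons another split gave more genes than the real one. In HC+RSV against HC, HC+RSV+EZE against HC+EZE and livers with rosuvastatin against livers without, 0 genes passed (limma, 235, 151 and 209 at an unadjusted p under 0.05). Every split gives at least 0 genes, so the share of splits could not test chance there. The highest other counts were 1145, 3 and 1094. For the interaction (0 genes, 152 at an unadjusted p under 0.05) no splits were made. Residuals of a fit in which the drug effects add up were shuffled over the arrays, with a highest count of 1732. In the comparisons averaged over the other drug, labels were shuffled only between groups alike in that other drug. The splits that called many genes point to a structure of the samples that does not follow the groups.

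In HC+RSV, 2 livers had levels of Ciart and Usp2 near those with ezetimibe, an observation made after their values were seen. Replicates 7 and 8 stood at 6.90 and 6.99 for Ciart and at 8.71 and 8.78 for Usp2, above the highest HC liver (5.85 and 7.29). Both lay at position C, the highest position among arrays without ezetimibe, as did replicates 5 and 6, which stood at 5.26 and 5.58 for Ciart and at 5.55 and 7.20 for Usp2.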
